A study of Arabidopsis thaliana with 12 samples.

How the data were processed

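Total RNA of Arabidopsis thaliana toc34 mutants (6 samples) and of wild type (6 samples), both in Columbia 0 per the labels, was measured on 1 array per sample. Genotype and replicate number were taken from the sample titles. The deposited value of each spot is an intensity on a linear scale, judged from the values themselves because no unit was stated with the table. Its lowest value is 0 and its highest, which 6 spots reached on at least 1 array, is a ceiling just under 100. The ceiling held 20 values in toc34 and 1 in wild type, and such values are lower bounds. How the authors subtracted background, scaled and labelled, and with which scanner and software, is not given in the sources used here. An unstated background subtraction could set dim spots to 0 and raise the spread of the values just above it. The column medians of log2 intensity differed by up to 0.50, so the table was not fully scaled between arrays. Differences between genotypes in deposited intensity therefore carry the difference in scale, and fold changes were computed after normalization.

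Values of 0 were taken as missing, since they have no logarithm, and between 465 and 655 spots per array were at 0. The log2 intensities were quantile-normalized between arrays, because the median gap was over the 0.2 allowed. A spot needed at least 4 measured values in each genotype, which left 2768 of 3439 spots for the tests and 671 untested, among them 104 at 0 on all 12 arrays. Genotypes were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with no covariate and with Benjamini-Hochberg adjustment over all tested spots at a threshold of 0.05. All p-values are two-sided unless stated. Log2 differences are toc34 minus wild type. Intensities printed with an SD are the deposited values before normalization, and the number of arrays limits their precision.

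Gene names rest on the annotation of the array platform, which is from 2016, updated through gene identifiers with a RefSeq gene table of TAIR10.1. A single gene was listed for 692 spots, of which 690 matched a locus of that table. No gene was named from a spot with several genes. No genome build was named for the array, so no coordinates are given.

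The design, gene lists, named-gene rule and first set of alternatives were fixed before the data were examined. Named genes were the 12 largest increases and 12 largest decreases in log2 difference among called spots with a single gene and a mean level at or above the 25th percentile, the up to 4 members with the smallest p from each list with at least 5 measured members, and genes of the lists singled out by a check. All 5 tested plastid ribosomal protein genes and all 8 tested photosynthesis genes were then given, and the photosynthesis list itself was formed after part of its values had been seen. The 17 fixed lists covered the light-harvesting complex, photosystems I and II, electron transport and ATP synthase, the Calvin cycle, photorespiration, tetrapyrroles, protein import, chaperones and proteases, plastid ribosomal proteins, carotenoids and antioxidants, starch, fatty acids, sigma factors, stress and senescence, cytosolic reference genes, and markers of seed, root and flower. Lists were tested with camera of limma at a preset correlation between genes of 0.01, over spots measured on all 12 arrays, with Benjamini-Hochberg adjustment over the 2 lists tested. The estimated correlation and fry were run beside it. The result of fry, which asks whether the genes move one way on balance and does not set them against other genes, was an adjusted p of 2.31e-06 for the photosynthesis list and 0.544 for the plastid ribosomal proteins.

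Replicates were compared before they were used. Across spots, wild-type arrays with neighbouring numbers (1 and 2, 3 and 4, 5 and 6) correlated at 0.943 to 0.966 and other wild-type arrays at 0.898 to 0.933. In toc34 these ranges were 0.848 to 0.900 and 0.785 to 0.816, and across genotypes 0.751 to 0.804. Spots are not independent replicates, so no p is attached. Neighbouring numbers were therefore also taken as a random block, with a consensus correlation of 0.535 from duplicateCorrelation (statmod 1.5.0), and averaged. The deviations of same-numbered arrays from their genotype means correlated at 0.12, 0.15, 0.22, 0.26, 0.16 and 0.18 for numbers 1 to 6, all over the 0.1 set for a pairing. The numbers were thus treated as pairing the arrays, a pairing that comes from the values and not from the labels, and a fit with the replicate number as a block was run beside the main design, which has none. Correlations of differently numbered arrays across genotypes are not set beside these, so a pairing number by number is not shown. Summed intensities were highest for numbers 3 and 4 in both genotypes, at 3515 and 3553 in wild type and 3102 and 3105 in toc34. If neighbouring numbers are repeats, that block counts them as separate pairs.

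The procedure was tested on simulated data for the comparison of toc34 with wild type, with 2768 spots, 200 of them changed, in 5 runs. With independent arrays it recovered 49.1% of 2-fold and 84.8% of 4-fold changes, with 5.76% and 4.93% of the calls false. With neighbouring numbers correlated at the observed 0.535, it recovered 55.3% and 87.1% with 25.8% and 24.0% of the calls false. Under that correlation the random block recovered 34.4% and 79.2% with 4.44% and 5.26% false, and averaging recovered 0.1% and 68.2% with 0% and 3.40% false. The simulated errors had the same spread in both genotypes, and the simulated values were not normalized. In the data the median SD of toc34 over that of wild type was 1.89, and 36.0% of the spots were called. These rates may therefore not hold for the data.

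Alternatives tried were the deposited scale, centring on array medians, cyclic loess, an offset of 0.0411 before the logarithm, filters on level and on missing values, each array left out in turn, the replicate number as a block, neighbouring numbers averaged, as a random block or as 3 fixed blocks, each pair of numbers alone, values at the ceiling set to missing, position classes centred, trend and robust variance, array weights and a threshold of 0.01. The position classes were inferred from the spot numbers and not from a layout of the array. TOC34, TOC33 and the cytosolic reference genes had no spot of their own and were left out.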

Results

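RNA from the Arabidopsis thaliana toc34 mutant and from wild-type plants of the same background, the ecotype Columbia 0, was measured on 12 arrays, 6 for each genotype. The mutant is described in the labels as impaired in the import of proteins through the outer membrane of the chloroplast envelope, where TOC34 is known as a GTP-binding receptor of the import machinery. Each array gave an intensity for 3439 spots. The summed intensity per array ran from 1988 in toc34 replicate 5 to 3553 in wild-type replicate 4, and between 2784 and 2974 spots per array had a value above 0. The platform annotation paired 692 spots with a single gene and 870 with several genes, and it listed none for the other 1877, so that most spots stayed unnamed here. No spot was annotated to TOC34 or to its paralog TOC33 alone, so both genes are not analysed here and the genotype labels were not checked against the mutated gene. The labels do not say which tissue was used or whether the 6 arrays of a genotype came from separate plants, so the p-values measure the spread between these arrays, which may be technical.

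The comparison of toc34 with wild type asks which transcripts differ in a plant with impaired import into the chloroplast. The highest increase among the named genes was that of AT1G02020, which rose 19.6-fold in toc34 (log2 difference 4.3, SE 0.24, limma adjusted p = 2.87e-07), from a deposited intensity of 0.144 ± 0.0119 to 2.62 ± 0.443 (SD, n = 6 arrays each). AT2G36480 rose 14.9-fold (3.89, SE 0.13) and AT1G06730 rose 6.61-fold (2.72, SE 0.21), the latter from 1.32 ± 0.2 to 7.15 ± 0.723. PAC, the PALE CRESS gene, which is needed for chloroplast development, rose 3.80-fold (1.93, SE 0.17), from 0.336 ± 0.0563 to 1.17 ± 0.253. AGL103, a MADS-box transcription factor, rose 4.69-fold (2.23, SE 0.18).

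The other 7 of the 12 named increases were AT2G46300 (log2 difference 2.60), AT2G28200 (2.57), AT3G26580 (2.01), AT5G42070 (1.98), AT3G09250 (1.76), AT5G34870 (1.74) and AT3G44570 (1.61). AT2G28200, which encodes a zinc finger protein, was dim and was listed at 0 on wild-type replicates 3 and 4, so its difference rests on the other 4 wild-type arrays and was 2.09 with an offset added before the logarithm. The limma adjusted p of these 7 genes lay between 6.43e-07 for AT3G26580 and 0.00114 for AT5G42070.

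Among the decreases, AT5G05400, a gene of the NB-LRR disease resistance class, fell 8.94-fold in toc34 (log2 difference -3.16, SE 0.49, limma adjusted p = 0.000364), from an intensity of 0.626 ± 0.195 to 0.0866 ± 0.0677 (SD, n = 6 arrays each). AT5G64150 fell 8.16-fold (-3.03, SE 0.45) and AT1G06510 fell 8.10-fold (-3.02, SE 0.32). These 3 genes were dim in toc34, and with an offset added before the logarithm their differences were -2.44, -2.22 and -2.40. AILP1 fell 5.62-fold (-2.49, SE 0.32), from 0.554 ± 0.0522 to 0.106 ± 0.0682. AT2G35390, a ribose-phosphate pyrophosphokinase that makes the precursor of nucleotides, fell 4.36-fold (-2.12, SE 0.21), and AT1G13370, a histone H3 gene, fell 3.46-fold (-1.79, SE 0.17).

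The remaining 6 named decreases were AT5G52530 (log2 difference -2.28), AT3G27550 (-2.24, or -1.60 with the offset), AT3G27110 (-2.12, listed at 0 on toc34 replicate 5 and missing there), AT5G56070 (-1.97), AT1G51550 (-1.89) and AT1G64430 (-1.80). With neighbouring replicate numbers treated as a random block, 22 of the 24 named increases and decreases kept a limma adjusted p under the threshold of 0.05, and AT3G27550 (0.0732) and AT1G51550 (0.0588) lost it. All 24 kept it with neighbouring numbers averaged. The direction was the same within replicates 1 and 2, within 3 and 4 and within 5 and 6 for these genes, apart from AT2G28200, which was measurable in 2 of these 3 pairs. The genes were picked for large differences on these same arrays, and only for AT3G27550 did the values of the genotypes overlap. For the others the direction within pairs was thus fixed in advance, and the calls kept after averaging rest on the same arrays.

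**Figure D1:**
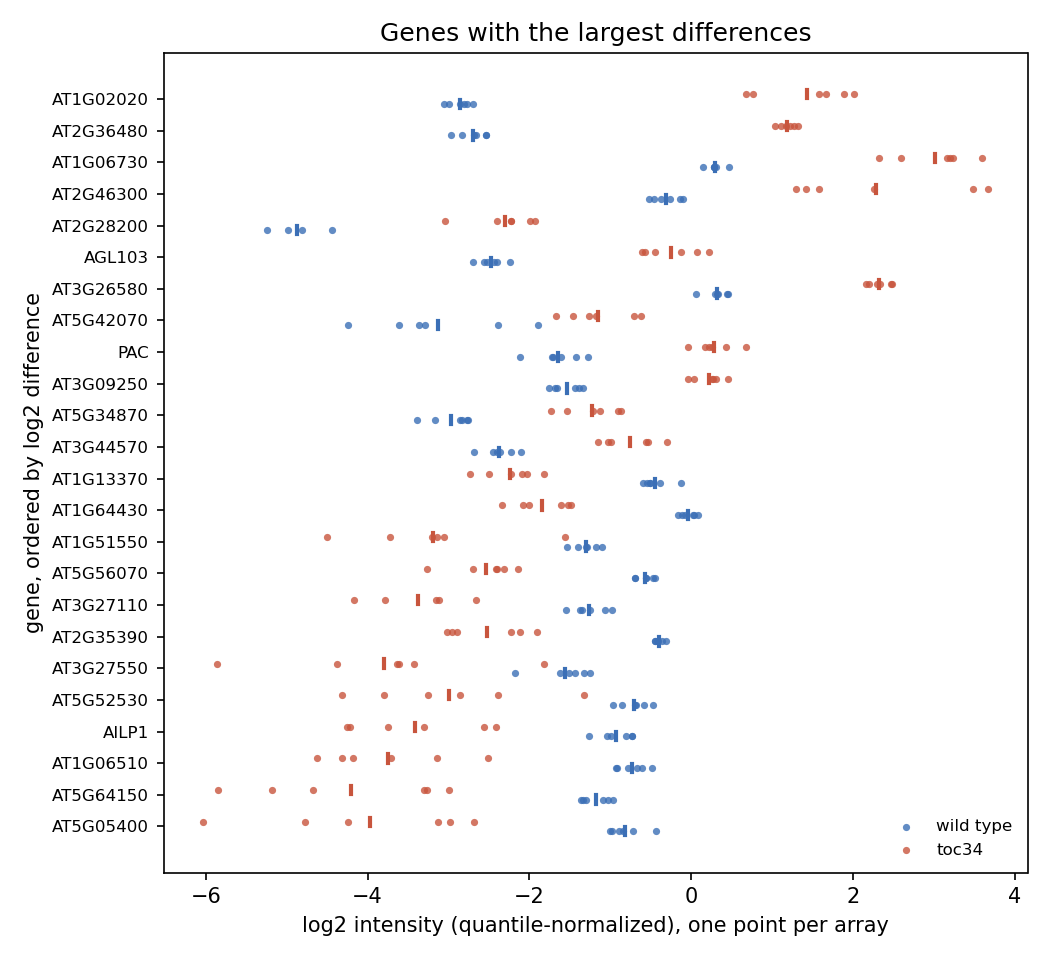
Log2 intensity after quantile normalization (horizontal axis) for the 12 genes with the largest increase and the 12 with the largest decrease (vertical axis), with 1 point per array, wild type in blue, toc34 in red and a bar at each mean. The points of both genotypes lie apart for AT1G02020 (log2 difference 4.3) and AT2G36480 (3.89), while those of AT3G27550 (-2.24) overlap.

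Across the array, 475 spots rose and 522 fell in toc34, 997 or 36.0% of the 2768 spots tested (limma, Benjamini-Hochberg adjusted p under 0.05), and 580 of them differed more than 2-fold. Among spots with a single named gene, 100 rose and 104 fell, of 551 tested. Arrays with neighbouring replicate numbers resembled each other more than other arrays of their genotype, so the 12 arrays may not be independent. With neighbouring numbers as a random block 317 spots rose and 308 fell, and with neighbouring numbers averaged to 3 values per genotype 187 rose and 194 fell. With averaging and the replicate number as a block together, 115 rose and 88 fell.

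**Figure D2:**
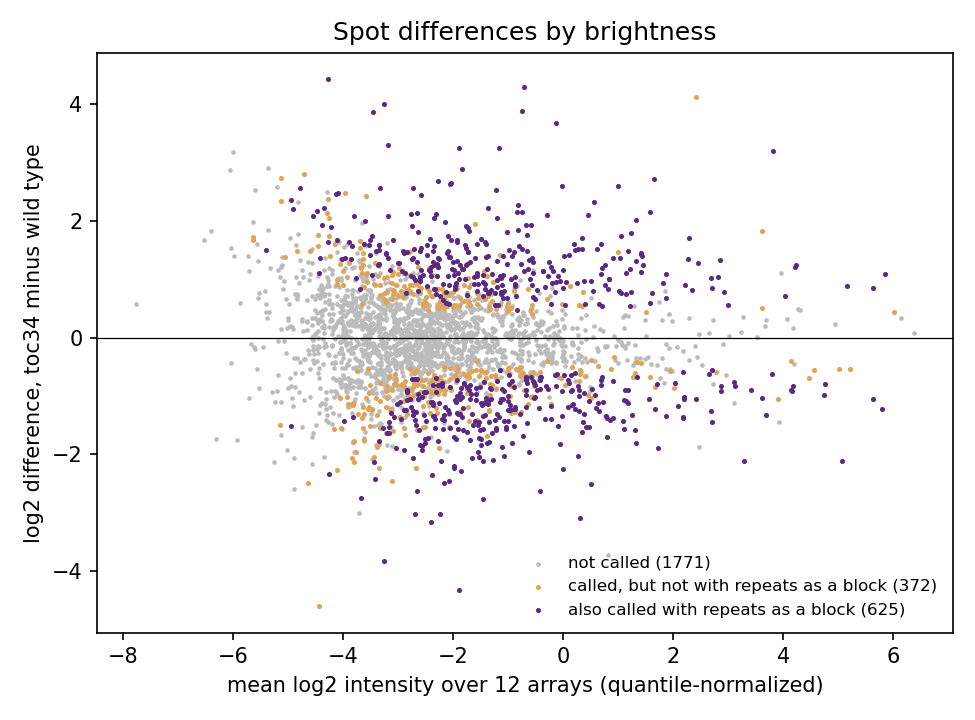
Log2 difference of toc34 minus wild type (vertical axis) against mean log2 intensity over 12 arrays (horizontal axis) for the 2768 tested spots. Purple points are the 625 spots called also with neighbouring replicate numbers as a random block, orange points the 372 called with all 12 arrays taken as independent but not with that block, and grey points the 1771 spots not called.

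The balance of increases and decreases was close to even after quantile normalization, which gives every array the same distribution of values and so itself favours an even split. Spots that rose made up 47.6% of those called, and 47.8% of all tested spots had a positive difference, with a median log2 difference over all spots of -0.05. The split depended on the scaling. On the deposited scale 335 spots rose and 590 fell, so that 36.2% of the calls were increases, and the median over all spots was -0.20. With each array centred on its own median 441 rose and 559 fell, or 44.1% increases, with a median of -0.10.

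Of the nuclear genes on the fixed photosynthesis lists, 8 were tested, and 3 of them fell in toc34. Of all 2768 tested spots 36.0% were called, 475 higher and 522 lower, so the number of calls alone does not set these genes apart. PSBY, a small subunit of photosystem II, fell 2.66-fold (log2 difference -1.41, SE 0.12, limma adjusted p = 4.11e-06), from an intensity of 3.16 ± 0.579 to 1.07 ± 0.314 (SD, n = 6 arrays each). PRK, the phosphoribulokinase of the Calvin cycle, fell 2.19-fold (-1.13, SE 0.21, adjusted p = 0.00132), from 2.43 ± 0.600 to 1.02 ± 0.264. PSBW, a further photosystem II subunit, fell 1.44-fold (-0.53, SE 0.18, adjusted p = 0.0379), from 49.1 ± 8.78 to 21.0 ± 4.07. These intensities lie further apart than the fold. The difference of PSBW was -1.23 on the deposited scale and -1.13 with each array centred on its median. Its smaller fold thus came mostly with quantile normalization and not from the difference in scale between arrays. The call of PSBW ended without wild-type replicate 1 (adjusted p = 0.0648), 2 (0.0803), 4 (0.0588) or 6 (0.0733) or toc34 replicate 2 (0.0610), 3 (0.0658) or 4 (0.0682), and with values at the ceiling set to missing, where its difference was -0.24 (adjusted p = 0.224). None of its own values was at the ceiling, as they ran from 17.1 to 64.1. That change therefore came with the quantile normalization, which was run again without the ceiling values of other spots. LHB1B2, a light-harvesting chlorophyll-binding protein also called LHCB1.5, had a difference of -0.45 (SE 0.19, adjusted p = 0.0809), and PSAN of photosystem I of -0.39 (SE 0.17, adjusted p = 0.0909). AT1G74470, the geranylgeranyl reductase of chlorophyll synthesis, had a difference of -0.54 (adjusted p = 0.0562), and CHLM, the magnesium-protoporphyrin methyltransferase, of -0.67 (adjusted p = 0.330), which was -0.15 without toc34 replicate 6. PSB27, a photosystem II assembly factor, had a positive difference of 0.41 (adjusted p = 0.559), from 0.23 without toc34 replicate 6 to 0.75 without toc34 replicate 1.

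Together these 8 genes made up the tested members of a photosynthesis list, the union of 6 lists fixed earlier, formed once it was seen that each had fewer than 5 measured members. Part of the list's values had been seen by then, so its set test is not that of a list fixed in advance. Of the 8, 3 fell and 0 rose over all spots tested, and 4 fell and 0 rose when adjusted over the list alone. The list lay lower than the other spots by camera with the preset correlation (adjusted p = 0.0299 over 2 lists), and adjusted p = 0.0911 with an estimated correlation, which ends the call. The list's call also ended within replicates 1 and 2 (adjusted p = 0.0906), within 3 and 4 (0.0818) and within 5 and 6 (0.0726), in fits of 2 arrays per genotype where the list's median was -0.50, -0.75 and -0.55, against -0.54 over all arrays. With all arrays kept, it ended by camera with values at the ceiling set to missing (adjusted p = 0.0633, median -0.41) and with averaging and the replicate block together (0.0521). No value of the 8 genes was itself at the ceiling, so none of theirs was set to missing. The calls of single genes depended on the treatment of neighbouring arrays: averaged, PRK had an adjusted p of 0.0519 and PSBW of 0.193, and PSBW had 0.168 with the random block and 0.0573 with the replicate number as a block. The call of PRK also ended within replicates 1 and 2, at a difference of -0.51 (limma adjusted p = 0.130), and within 3 and 4, at -1.30 (0.0606). Within 5 and 6 its difference was -1.58. Relative to the median of all spots, the list's median was -0.49 after quantile normalization, -0.70 on the deposited scale and -0.71 with arrays centred on their medians. On each of these last 2 scales 6 of the 8 genes fell, with LHB1B2, PSAN and AT1G74470 added to the 3 above.

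**Figure D3:**
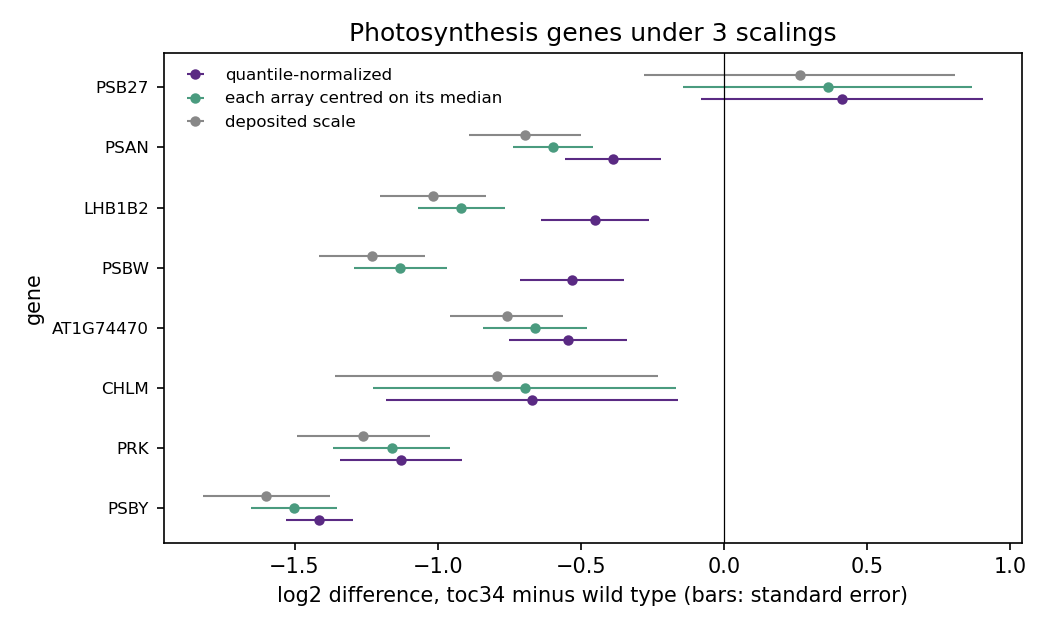
Log2 difference of toc34 minus wild type with its standard error (horizontal axis) for the 8 photosynthesis genes (vertical axis) under 3 scalings, over 6 arrays per genotype. PSB27 lies above 0 (0.41 after quantile normalization, 0.26 on the deposited scale) and the other 7 genes below 0 under each scaling, with PSBW at -0.53 after quantile normalization and -1.23 on the deposited scale.

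Some spots were annotated to several genes that all stood on the same fixed list. A spot shared by 3 light-harvesting genes fell 1.87-fold in toc34 (log2 difference -0.90, SE 0.18, limma adjusted p = 0.00204), and a spot shared by 2 genes of photosynthetic electron transport and ATP synthase fell 2.08-fold (-1.06, SE 0.21, adjusted p = 0.00165). Averaging neighbouring arrays raised these adjusted p-values to 0.0597 and 0.0673. A spot of 2 tetrapyrrole genes had a difference of -0.34 (adjusted p = 0.116), and 2 spots of carotenoid and antioxidant genes had differences of 0.18 (adjusted p = 0.698) and -1.20 (adjusted p = 0.135).

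Genes for plastid ribosomal proteins went both ways. AT3G54210, the protein L17 of the large subunit, fell 2.1-fold in toc34 (log2 difference -1.07, SE 0.18, limma adjusted p = 0.000726), and AT5G65220, the protein L29, rose 2.11-fold (1.08, SE 0.21, adjusted p = 0.00161). With neighbouring arrays averaged the call of AT5G65220 ended (adjusted p = 0.0667), and that of AT3G54210 ended with averaging and the replicate block together (adjusted p = 0.0688). AT4G01310 had a difference of -0.41 (adjusted p = 0.0715), AT3G13120 of 0.59 (adjusted p = 0.283; 0.32 without wild-type replicate 4 to 0.80 without toc34 replicate 1) and AT1G29070 of -0.16 (SE 1.0, adjusted p = 0.918). The sign of AT1G29070 turned with single arrays, from -0.77 without toc34 replicate 5 to 0.82 without toc34 replicate 4. It was dim, with a mean deposited intensity of 0.0607 in wild type and 0.0789 in toc34. Of the 5 tested members 1 rose and 1 fell over all spots, where 36.0% of all tested spots were called. When adjusted over the list alone, 1 rose and 2 fell. The list did not differ from other spots by camera (adjusted p = 0.898 with the preset correlation and adjusted p = 0.921 with an estimated correlation, over the 4 members measured on all arrays). Its median was -0.16, its mean 0.0072 and the direction of the test downward, which turned upward on the deposited scale and without toc34 replicate 1. The median was 0.57 without toc34 replicate 4.

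The other fixed lists had too few measured members for a set test. The light-harvesting list had 1 tested gene, photosystem I 1, photosystem II 3, the Calvin cycle 1 and tetrapyrrole biosynthesis 2, and these are the 8 genes given above. Electron transport and ATP synthase, photorespiration, chloroplast protein import, chloroplast chaperones and proteases, carotenoids and antioxidant defence, starch metabolism, plastid fatty acid synthesis, sigma factors, stress and senescence, cytosolic reference genes, and markers of seed, root and flower each had 0 genes on spots of their own.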

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

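None of the tests in this part was chosen after the result was seen, apart from the choice to include all 8 photosynthesis genes and a further plastid ribosomal protein gene, AT1G29070. Each of 77 groups of 6 arrays, made of the named genes and 3 array summaries (total, spots measured, median) in each genotype, was searched for an array far from the others, with a critical ratio of gap to range of 0.625. An array stood apart in 2 groups, where chance alone gives about 3.85.

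CHLM, the magnesium-protoporphyrin methyltransferase, had a ratio of 0.647 in toc34, where replicate 6 lay at a log2 intensity of -4.93 and the other 5 arrays between -2.48 and -1.15. AT3G13120, the plastid ribosomal protein S10, had a ratio of 0.670 in toc34, where replicate 1 lay at -4.66 and the others between -3.56 and -3.02. The deposited intensities on these arrays, 0.0260 for CHLM and 0.0342 for AT3G13120, lay below the offset of 0.0411, so both values were dim.

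Among the spots too often at 0 to be tested, 5 were measured on all 6 wild-type arrays and were listed at 0 on all 6 toc34 arrays, and 0 spots showed the reverse. AT4G12270 had an intensity of 0.365 ± 0.118 in wild type (SD, n = 6), AT3G50350 of 0.204 ± 0.0917 and AT4G03150 of 0.0735 ± 0.0187. The other 2, which carry no gene name here, had 0.414 ± 0.104 and 0.0550 ± 0.0288. Only 2 of the 5 spots had every wild-type value above the median of measured spots on its array. AT4G03150 and the dimmer unnamed spot reached at most 0.0952 and 0.0789 in wild type. No fold is given against values of 0.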

How the results depend on the processing

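Chosen after the data were seen were the random block, the 3 fixed blocks, the fits within a pair of numbers, averaging with the block, cyclic loess, the missing ceiling values, the centred positions, the averaged list with an estimated correlation, the photosynthesis list and its versions with spots of several genes. Of 1137 values of named genes under the alternatives, 1063 kept direction and side of the threshold, 38 lost the call, 29 gained it and 7 changed sign. The count of 997 stayed within 1.5 times (742 to 1188) except as follows. It was 381 (187 higher, 194 lower) with neighbouring numbers averaged, 203 (115 and 88) with averaging and block, 625 (308 lower) with the random block, 574 (288 and 286) within numbers 5 and 6, and 620 (303 and 317) at a threshold of 0.01. Averaging and single pairs leave fewer values. The replicate block gave 1010 calls, 914 of them among the 997, and of the named genes ended only the call of PSBW (adjusted p = 0.0573). The share of increases among calls was 36.2% on the deposited scale, 44.1% centred on medians, 44.4% with array weights, 51.3% within numbers 1 and 2 and 56.7% averaged with block. The share of positive differences was 41.0% on the deposited scale, 45.4% centred, 48.8% with the offset, 45.0% above the 25th percentile of level, 49.0% with 2 values per genotype, and 46.9% to 48.4% with 1 array left out, lowest without wild-type replicate 3. The photosynthesis list (adjusted p 0.00423 with spots of several genes, otherwise 0.00454 to 0.0471 where its call held with camera, 0.0234 to 0.0387 with 1 array left out) lost it within numbers 1 and 2 (0.0906), 3 and 4 (0.0818) and 5 and 6 (0.0726), averaged with block (0.0521), with missing ceiling values (0.0633), with an estimated correlation (0.0911) and averaged with it (0.160), and with spots of several genes in these last 2 settings (0.0929 and 0.210). The plastid ribosomal list was never called, and the direction of its camera test turned upward on the deposited scale (0.984), within numbers 3 and 4 (0.693) and 5 and 6 (0.544) and without toc34 replicate 1 (0.922), in a range of 0.840 to 0.984 with 1 array left out. Its median turned positive with the offset (0.086), cyclic loess (0.07), within numbers 5 and 6 (0.23) and without wild-type replicate 2 (0.049), toc34 replicate 2 (0.12) or 4 (0.57), and was negative in the other settings it was computed for. AT1G29070 (-0.16) turned to 0.086 with the offset, 2.29 within numbers 5 and 6 (adjusted p 0.0273, against -3.49 and 0.0396 within 3 and 4), and 0.049, 0.12 and 0.82 without wild-type replicate 2, toc34 replicate 2 and toc34 replicate 4, in a range of -0.77 to 0.82 with 1 array left out. PSB27 and AT3G13120 were at -0.56 and -0.40 within numbers 1 and 2 (0.147 and 0.516) and at 0.96 and 1.94 within 3 and 4 (0.0406 and 0.0230). PSBW lost its call with array weights (0.0761). LHB1B2 gained one without toc34 replicate 2 (0.0227), with trend and robust variance (0.0403), cyclic loess (0.00772) and centred positions (0.0185), PSAN with trend and robust variance (0.0483), fixed blocks (0.0177) and centred positions (0.0222), AT1G74470 without toc34 replicate 1 (0.00800) and with trend and robust variance, array weights, offset, level filter, fixed blocks and centred positions (0.0219 to 0.0421), and AT4G01310 without wild-type replicate 1 (0.0496) or 2 (0.0446), with fixed blocks (0.0416) and centred positions (0.0115). Apart from fewer values, the cause was not tested. Alternatives for TOC34, TOC33 and the cytosolic reference genes, with no spot of their own, were not run. Too many values at 0 left 671 spots untested.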

Other observations

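Chosen after the result was seen were the genes of the next paragraph, the test of repeats counted as replicates, the test of noise between repeats and the test of genes near TOC34.

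Further genes with a symbol went both ways, and no test of a common theme was run on them. NTRC, the plastid NADPH-thioredoxin reductase, fell 2.97-fold (log2 difference -1.57, SE 0.17, limma adjusted p = 1.91e-05), and 2 pentatricopeptide repeat proteins that act on chloroplast transcripts fell as well, OTP70 by 1.52 and CRR21 (-1.07) on the log2 scale. RAP74, a subunit of a general transcription factor of RNA polymerase II, had a difference of -1.37 and ILA of -1.06. Among the genes that rose, CSLA01, of the cellulose synthase-like family, rose 4.66-fold (2.22, SE 0.23), SWAP70 3.06-fold (1.61), DI21, a drought-induced gene, 2.86-fold (1.52) and CCL 2.51-fold (1.33), the last from an intensity of 5.02 ± 0.871 to 10.1 ± 1.74 (SD, n = 6). CSLA01 and SWAP70 were dim, with wild-type intensities of 0.0268 ± 0.00378 and 0.0531 ± 0.0146. Both lay below the level required of the named genes, so their folds are uncertain. GLDH, the last enzyme of ascorbate synthesis, rose 2.25-fold (1.17), PPDK, pyruvate orthophosphate dikinase, 2.06-fold (1.04), the glycosyl hydrolase genes GH9B11 and GH9B12 2.07-fold and 1.89-fold, and LPA19, a factor of photosystem II assembly, 1.87-fold (0.90). All of these genes passed with neighbouring arrays as a random block, and GLDH, PPDK, GH9B11, GH9B12 and LPA19 did not with neighbouring arrays averaged (adjusted p 0.0542 to 0.121). SECE1, a subunit of the thylakoid protein translocase, rose 1.54-fold (0.63, adjusted p = 0.0269), a call that ended with the random block (adjusted p = 0.124). Called genes with a symbol that are not described above also lost the call with the random block. These were AGL54, LpxA, SIS, HEMA3, CYN, IAA31, FBL17 and CBL, with a limma adjusted p from 0.0501 for IAA31 to 0.212 for FBL17.

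The count of 997 called spots was not matched by chance groupings of the arrays: of 100 of the 462 splits into 6 and 6, 1 gave as many, the real one, and the highest other split gave 1 call. Of the 32 splits that part all 6 same-numbered pairs, which exchange the genotypes of some numbers, again 1 gave as many and the highest other gave 1. Both sets of splits treat the 12 arrays as exchangeable, and most of them separate arrays with neighbouring numbers. If neighbouring numbers are repeats, these splits cannot exclude chance. With neighbouring numbers averaged the real split called 381 spots and the highest other 0. There 1 of 10 splits reaching the real count is the smallest share possible and cannot fall under 0.05, so these splits cannot decide. The 381 calls, 378 of them among the 997, argue against repeats within pairs of neighbouring numbers as the source of all calls. Part of the 997 may still come from such repeats. Averaging could not remove repeats shared by all 6 arrays of a genotype. Position on the array was inferred from the spot numbers, without a layout of the array. After 12 classes of spot number, taken as classes of position, were centred the count was 996, or 99.9%, with 909 spots shared with the 997. After classes within blocks of spot numbers were centred it was 944, or 94.7%, with 792 shared. Offsets shared by these classes are thus not the source of most calls, while the spots no longer called may depend on them. Other effects of position stay open, because centring removed only part of the pattern and spot numbers may not follow the layout. The correlation of log2 differences between spots 6 numbers apart was 0.109 before centring. It was 0.089 after centring the 12 classes and 0.056 after centring the classes within blocks. The genotype and an unrecorded difference in growth or RNA preparation between the plants stay open and untested.

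The lower photosynthesis genes had a median log2 difference of -0.54, and centring the 12 position classes, inferred from spot numbers, left 119.9% of it. This argues against offsets of these classes as the cause, and cannot judge other effects of position, which the centring left in place. For a trend with brightness, 10000 random lists matched on brightness were drawn. Their medians ran from -0.87 to 0.75 in their middle 95%, around -0.18, and the list's median lay at percentile 18.9. With arrays centred on their medians the list's median of -0.81 lay at percentile 9.35, and the matched lists centred on -0.30. Equally bright spots were thus typically shifted less than the list, but the wide spread of the matched lists does not set it apart. A trend with brightness and a lower transcript level in the mutant both stay open. PSBY differed between the genotypes on its own (limma adjusted p = 4.11e-06), but that test does not address brightness.

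The toc34 arrays varied more than the wild-type arrays, with a median SD of log2 intensity of 0.526 against 0.278 over 2337 spots, a ratio of 1.89, and 82.4% of these spots had the higher SD in toc34. The ratio was at least 1.72 in each of 10 classes of equal brightness, which argues against lower signal as the cause, and at least 1.75 with any pair of arrays left out, which argues against a single deviating pair. Noise between repeat measurements stays open as a candidate source: between neighbouring numbers the SD was 0.331 in toc34 and 0.166 in wild type, a ratio of 1.99. The averages of neighbouring numbers also varied more in toc34, with a ratio of 1.82, so that a larger spread between mutant plants stays open too, untested.

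Genes near the mutated locus were tested for a hypothesis that differences linked to TOC34 by descent may add to the calls. Among the 200 genes on either side of TOC34, 5 of 7 tested genes were called (71.4%), against 199 of 542 elsewhere (36.7%), with a one-sided Fisher's exact p of 0.0700, which leaves it undecided with so few genes. The 5 were AT5G05400 (log2 difference -3.16), AT5G06010 (1.54), AT5G03900 (-0.71), AT5G05330 (0.62) and PRA1.B3 (-0.53). The calls of AT5G05330 and PRA1.B3 ended with neighbouring arrays as a random block (adjusted p 0.0768 and 0.0943), so the share rests in part on calls that depend on the arrays being independent.

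APTX, an aprataxin-like gene, had an intensity of 99.4 on the array of wild-type replicate 1 and was listed at 0 on the other 11 arrays.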
